A study of Homo sapiens with 12 samples.

How the data were processed

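Bulk RNA sequencing was made from Ishikawa and KLE cells, each untreated or after 24 h in 200 µM CuCl2, with 3 independent biological replicates per group per the labels. The labels call the control cells both untreated and vehicle; they are called untreated here. Per the labels' protocols, RNA was extracted with TRIzol, mRNA was enriched with an oligo(dT) kit, and paired-end reads of 150 bp were collected. Per the submitters' processing notes, the tools were fastp 0.18.0, Bowtie2 2.2.8, HISAT2 2.1.0, RSEM, DESeq2 and R 4.2.2 with genome build GRCh38.p14; what each tool was used for and the annotation release are not given in the sources used here.

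The deposited tables hold 3 units for 20332 genes. The authors' all-genes table gives expected counts, of which 12.8 to 14.1% per library are not whole, and TPM, abundances scaled to transcript length and library total. The raw count tables of each line, deposited as whole counts, hold those expected counts rounded by the authors, with differences of at most 0.5. The tables named for FPKM hold TPM per the file headers, and their columns add up as TPM do, so the alternatives planned on FPKM were run on the authors' TPM. Whole counts were used for all main results, and no per-sample column was left unused. Symbols are those of the deposited table; 617 genes have none and hold at most 0.21% of a library's counts, and 58 have a shared symbol. Coordinates and gene types come from the GENCODE annotation of GRCh38, matched by Ensembl ID (20304 IDs matched a named reference gene).

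Libraries held between 14050275 and 25057003 counts. CPM are counts scaled to library totals with TMM factors, and the error beside a mean is the SD of 3 libraries. The error beside a log2 fold change is an SE obtained from the edgeR F statistic, as the absolute change over the square root of F. It is too small where a group holds few counts, as for RRAD, MT1G, LHX1 and LRRTM4. For MT1G in KLE cells it is 0.29 around a value of 8.58, which is 11.23 without KLE control 3. Intervals of ratios from 1 to 3 control counts are 95% counting intervals and cover counting error only. Values of near-identical genes (HSPA1A and HSPA1B, HSPA6, the MT1 family, USP17L2, the AKR1 family) depend on how the authors' quantification shared reads among them.

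Differential expression was tested with edgeR 4.0.16 (TMM factors, filterByExpr, robust quasi-likelihood fit, two-sided, Benjamini-Hochberg adjusted p under 0.05) in R 4.3.3. Copper was compared with no copper in the 6 libraries of each line. The difference between the responses and the difference between the untreated lines were contrasts of a fit of all 12 libraries. In data simulated at the size and spread of each comparison, with 200 genes changed, edgeR recovered 76% (Ishikawa), 88% (KLE), 69% (response difference) and 81% (untreated lines) of genes changed 1.5-fold, and 5.3, 7.7, 8.1 and 4% of its calls were false. In the real data 9228 of 13359 genes were called in Ishikawa cells and 6617 of 13031 in KLE cells. With so many more genes called, these shares need not hold for the real calls.

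The comparisons, tests, gene lists, rule for named genes and most alternatives were fixed before the data were examined. The 31 lists (766 genes, 765 in the tables) were metallothioneins, copper transport, zinc transport, cuproptosis, lipoylation and TCA cycle, iron-sulfur assembly, heat shock, NRF2 targets, integrated stress response, unfolded protein response, p53 targets, G1 and S phase, G2 and M phase, cholesterol synthesis, iron and ferroptosis, nuclear and mitochondrially encoded oxidative phosphorylation, proteasome, autophagy, NF-kB and inflammation, immediate-early, hypoxia, matrix and mesenchymal, epithelial, estrogen-responsive, apoptosis, ribosomal protein and replication-dependent histone genes, and fibroblast, leukocyte and endothelial markers. Lists with at least 3 tested genes were tested with camera (limma 3.58.1, voom, preset correlation 0.01, adjusted over the lists), again with an estimated correlation, and with fry, which asks whether a list's genes move one way without reference to other genes. Members were counted over all genes tested and adjusted over the list alone.

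Named genes were, for each line, the 8 protein-coding genes with the largest rise and the 8 with the largest fall among called genes with a mean of at least 5 CPM whose treated libraries all lay beyond the untreated ones; up to 2 called members of each of the 6 lists with the smallest camera p; all cuproptosis genes; and the called metallothioneins and copper transport genes. For the response difference 6 genes per direction were taken, and for the untreated lines 5. Some genes that this rule takes are not reported here. Other list members named as examples were chosen after their values were seen.

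Alternatives were RLE, upper-quartile and library-total scaling, CPM above 1 in 3 libraries or no count filter, an absolute log2 fold change of at least 1, DESeq2 1.42.0, limma-voom, limma on log2(TPM + 1) with TPM above 0.5 in 3 libraries or without a filter, and on log2(TPM + 0.1), a fit of all 12 libraries for the single lines, the replicate number as a block, and leaving out each library. Markers of stroma, plasma cells and glandular secretion were listed after the data had been seen. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and figures with matplotlib 3.10.9.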

Results

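RNA sequencing measured transcripts in Ishikawa and KLE cells, 2 human endometrial cancer lines, without treatment and after 24 h in 200 µM CuCl2. Each of the 4 groups held 3 libraries, 12 in all. The untreated Ishikawa libraries held 14747869, 25057003 and 16113128 counts and the copper-treated ones 17286059, 17716202 and 14050275. The untreated KLE libraries held 14182086, 16278623 and 15329378 counts and the copper-treated ones 16217747, 15241194 and 14748131. PAX8, a transcription factor of Müllerian epithelium, stood at 438 ± 22.1 TPM in untreated Ishikawa cells and 438 ± 16.2 TPM in untreated KLE cells (mean ± SD, n = 3). EPCAM, an epithelial adhesion molecule, stood at 841 ± 36.3 and 1040 ± 5.89 TPM (mean ± SD, n = 3), and ESR1, the estrogen receptor, at 0.124 ± 0.112 and 0.104 ± 0.0758 TPM (mean ± SD, n = 3). PGR stood at 0.144 ± 0.121 and 0.0793 ± 0.0693 TPM and CDH1 at 206 ± 7.09 and 196 ± 5.79 TPM (mean ± SD, n = 3). VIM stood at 6 ± 4.72 and 11.3 ± 2.62 TPM (mean ± SD, n = 3). The mitochondrial genome gave 6.8 ± 0.59% of counts in untreated Ishikawa cells, 6.3 ± 0.1% in copper-treated Ishikawa cells, 6.2 ± 0.5% in untreated KLE cells and 4.4 ± 0.34% in copper-treated KLE cells (mean ± SD, n = 3). Counts of 6 stromal transcripts, among them DCN and LUM, summed to between 257 and 1008 in 11 libraries and to 18 in Ishikawa control 2.

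**Figure D1:**
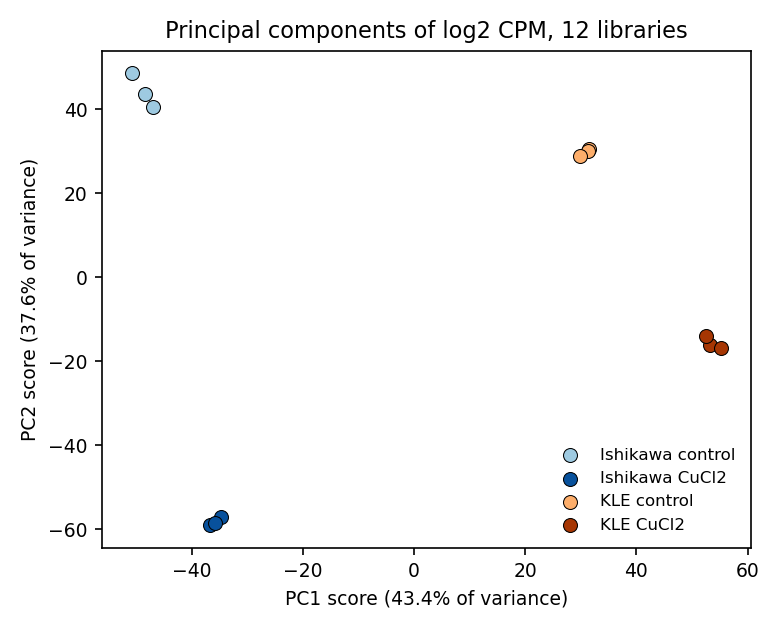
Principal components 1 and 2 of log2 CPM for the 12 libraries, 1 point per library, with the share of variance on each axis (43.4% and 37.6%). The lines lie apart on the first component and the copper-treated libraries lie below the untreated ones of their line on the second.

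Ishikawa cells with and without copper chloride were compared to ask which transcripts changed with 24 h of copper excess. HSPA6, an inducible HSP70 chaperone (ENSG00000173110, GRCh38 chromosome 1, 161524540 to 161526910), went from 0.922 ± 0.774 to 979 ± 63.9 CPM (mean ± SD, n = 3; log2 fold change 10.27 ± 0.36 SE). HMOX1, the heme-degrading enzyme heme oxygenase 1 (ENSG00000100292, chromosome 22, 35380361 to 35394214), went from 1.12 ± 0.154 to 214 ± 12.6 CPM (mean ± SD, n = 3; log2 fold change 7.61 ± 0.10 SE). HSPA1A, another inducible HSP70, rose by 6.83 ± 0.09 and CRYAB, a small heat shock protein, by 7.55 ± 0.21 on the log2 scale. RRAD, a Ras-related GTPase, rose by 9.93 ± 0.24 and ARC, an immediate-early regulator of the synaptic cytoskeleton, by 9.07 ± 0.16. USP17L2, a deubiquitinase from a multi-copy family, had 2 counts in the untreated libraries and 1264 in the treated ones, a ratio of 720 (95% counting interval 199 to 5960), and NEFM, a neurofilament subunit, had 2 and 608, a ratio of 347 (95.5 to 2870). Among genes that fell, NEURL1B, a ubiquitin ligase of the Neuralized family (ENSG00000214357, chromosome 5, 172641266 to 172691540), went from 38.8 ± 3.03 to 1.76 ± 0.436 CPM (mean ± SD, n = 3; log2 fold change −4.47 ± 0.14 SE). The log2 fold change was −3.14 ± 0.09 for LRRC32, a carrier of latent TGF-beta, −4.17 ± 0.18 for the semaphorin SEMA3D and −3.69 ± 0.17 for the plexin PLXNA4. The glutamate transporter SLC1A1 had a log2 fold change of −3.05, the chloride channel family member TTYH2 of −3.15, the membrane carboxypeptidase gene CPM of −2.80 and the receptor TNFRSF19 of −2.79. In each of these genes all 3 treated libraries lay beyond all 3 untreated ones, as the rule for naming them required, and their adjusted p ranged from 1.9e-16 for HMOX1 to 1.3e-05 for HSPA6 (edgeR quasi-likelihood test, Benjamini-Hochberg). Of 13359 genes tested, 4514 were higher and 4714 lower with copper, 9228 in all. With library totals in place of TMM factors the split was 3370 higher and 6068 lower, and with limma on log2(TPM + 1) it was 2989 and 5613. The median log2 change of all genes was −0.013 with TMM, −0.125 with upper-quartile factors and −0.167 with library totals. The highest ratios depended on single untreated libraries. Without Ishikawa control 2 the log2 fold change was 9.48 for HSPA6, 9.11 for RRAD, 7.54 for NEFM and 6.91 for CRYAB. Without Ishikawa control 3 it was 11.04 for HSPA6 and 11.21 for RRAD. In Ishikawa controls 1, 2 and 3, HSPA6 stood at 1.11, 0.0763 and 1.61 CPM (scaled with all 12 libraries). CRYAB stood there at 0.979, 0.229 and 1.26 CPM.

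Of 31 gene lists, 10 passed camera in Ishikawa cells at the preset correlation. All 31 members of the proteasome list rose, with a median log2 fold change of 0.97 (camera adjusted p = 1.1e-15; adjusted p = 0.0267 with an estimated correlation). In the wider KEGG proteasome set of 41 genes, tested after the data were seen, 38 rose and 2 fell (adjusted p = 2.5e-13, and 0.297 with an estimated correlation). Examples are PSMC4, an ATPase of the regulatory particle, which went from 84.1 ± 4.24 to 283 ± 7.13 CPM (mean ± SD, n = 3), and PSMD12, a lid subunit, which went from 122 ± 9.77 to 409 ± 18 CPM (mean ± SD, n = 3). Of the heat shock genes 28 rose, 0 fell and 2 were not called (median 1.37; adjusted p = 3.8e-13, and 0.153 with an estimated correlation), including HSPA1B by 4.93, HSPH1 by 4.13 and DNAJB1 by 3.76. The count was 29 adjusted over the list alone. Among NRF2 targets, the antioxidant genes bound by that factor, 30 rose, 1 fell and 3 were not called (median 1.41; adjusted p = 5.0e-12, and 0.0706 with an estimated correlation). SRXN1, which restores oxidised peroxiredoxins, rose by 2.54, GCLM, a subunit of the first enzyme of glutathione synthesis, by 2.37, and AKR1B10, an aldo-keto reductase, by 4.97. The NF-kB and inflammatory list had 16 members that rose and 0 that fell (median 1.40; adjusted p = 2.8e-05, and 0.0706 with an estimated correlation). In it the chemokine CXCL8 went from 2.87 ± 0.182 to 107 ± 6.22 CPM (mean ± SD, n = 3), and CCL20 rose by 4.12 on the log2 scale, by 3.43 without Ishikawa control 2 and by 4.83 without control 3. Integrated stress response genes rose in 25 cases and fell in 6 (median 0.60; adjusted p = 5.5e-05, and 0.426 with an estimated correlation), with ATF3, a stress-induced transcription factor, up by 3.48, the leucine sensor SESN2 by 2.47, PPP1R15A by 2.33, and DDIT4, an inhibitor of mTORC1, at −1.13. Autophagy genes rose in 18 cases and fell in 2 (median 0.42; adjusted p = 9.6e-05, and 0.0706 with an estimated correlation), including the lipidated autophagosome protein MAP1LC3B by 2.49. Genes of the endoplasmic reticulum unfolded protein response rose in 16 cases and fell in 3 (median 0.32; adjusted p = 0.00215, and 0.122 with an estimated correlation), with the chaperone HSPA5 at 0.69 and its cofactor SDF2L1 at −0.67. Immediate-early genes rose in 10 cases and fell in 2 (median 0.50; adjusted p = 0.0327, and 0.59 with an estimated correlation). FOSL1 rose by 2.80 and MYC fell by 1.67, and without Ishikawa control 1 this list had an adjusted p of 0.0565. In the G2 and M phase list 25 genes fell, 3 rose and 5 were not called (median −0.64; adjusted p = 4.0e-08, and 0.127 with an estimated correlation). The mitotic kinesin KIF20A went from 166 ± 3.39 to 36 ± 3.15 CPM and the securin PTTG1 from 89.9 ± 6.5 to 20.4 ± 3.03 CPM (mean ± SD, n = 3), while HMMR, CDCA3 and TTK had values of 0.32, 0.19 and 0.17. Adjusted over the list alone, 26 of these genes fell, and the other called lists gave the counts above.

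Copper-binding and copper-handling genes were compared in Ishikawa cells because they meet the added metal most directly. Of 12 metallothioneins, small metal-binding proteins, 4 passed the count filter, and all 4 rose (median log2 fold change 6.17; camera adjusted p = 7.6e-04, and 0.206 with an estimated correlation). MT2A (ENSG00000125148, chromosome 16, 56608199 to 56609497) went from 12.5 ± 3.62 to 841 ± 14.2 CPM and MT1X from 5.16 ± 1.07 to 226 ± 14.2 CPM (mean ± SD, n = 3). MT1G had 1 count in the untreated libraries and 424 in the treated ones, a ratio of 483 (95% counting interval 86.3 to 19100). Its fitted log2 fold change of 8.57 was 7.87 without Ishikawa control 2 and 10.34 without control 3, and with MT1G at the lower bound of the interval the median of the list is the same. Among the 10 genes of the cuproptosis list, which names the lipoylation and pyruvate dehydrogenase genes tied to copper-dependent cell death, 4 rose, 2 fell and 4 were not called (median 0.09; adjusted p = 0.362). When adjusted over the list alone, 4 rose and 1 fell. MTF1, the metal-responsive transcription factor, rose by 1.07 ± 0.06, the lipoamide dehydrogenase DLD by 0.85 ± 0.05 and PDHB, a subunit of pyruvate dehydrogenase, by 0.34 ± 0.06, and the cell cycle inhibitor CDKN2A fell by 0.60 ± 0.07 (log2 ± SE). LIPT1, a lipoyltransferase, had a value of −0.40 ± 0.17 and an adjusted p of 0.0445 (edgeR, Benjamini-Hochberg). This call of LIPT1 was marginal, with values of −0.38 and an adjusted p of 0.0539 with RLE factors, −0.39 and 0.153 with DESeq2, and −0.36 and 0.0751 with limma-voom. It was also lost without control 1 (−0.43, 0.0662), control 3 (−0.26, 0.19), and CuCl2 1 (−0.41, 0.0842), 2 (−0.35, 0.128) or 3 (−0.44, 0.0664). FDX1, the ferredoxin that reduces copper in this pathway, had a log2 fold change of −0.05 ± 0.10, the lipoyl synthase LIAS of −0.12 ± 0.09, DLAT, the lipoylated core of the complex, of 0.08 ± 0.05 and PDHA1 of 0.11 ± 0.05, with adjusted p between 0.0608 and 0.657 (edgeR). LIAS was called at −0.23 with upper-quartile factors and −0.28 with library totals, and PDHA1 at 0.13 with RLE factors. The median of this list was −0.02 with upper-quartile factors and −0.06 with library totals. In the copper transport list 5 genes rose, 7 fell and 9 were not called (median −0.02; adjusted p = 0.783). The copper importer SLC31A1 rose by 0.29 ± 0.05, the cytosolic superoxide dismutase SOD1 by 0.44 ± 0.05, the mitochondrial phosphate and copper carrier SLC25A3 by 0.40 ± 0.04, and the cytochrome oxidase assembly factors COX19 and COA6 by 0.67 each. The copper exporter ATP7B fell by 0.63 ± 0.07, the copper chaperones SCO2, COX11 and SCO1 had values of −1.14, −0.41 and −0.30, and the metalloreductases STEAP2, STEAP3 and STEAP1 of −1.37, −1.07 and −0.85. With limma on log2(TPM + 1), SLC31A1 was at 0.11 with an adjusted p of 0.164 and SLC25A3 at 0.15 with 0.169.

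**Figure D2:**
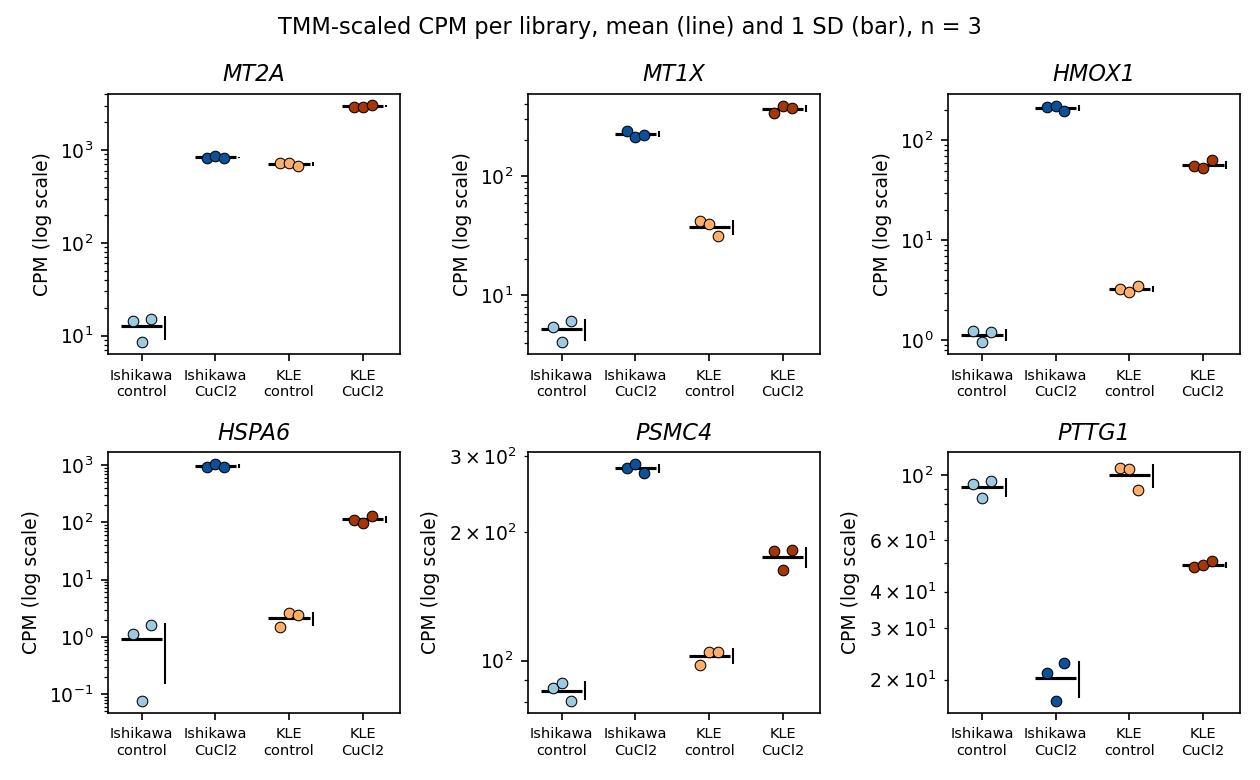
Level of 6 genes (MT2A, MT1X, HMOX1, HSPA6, PSMC4 and PTTG1) in each of the 12 libraries, as CPM on a log axis, with a line at the mean of each group and a bar of 1 SD (n = 3). MT2A is at 12.5 CPM in untreated Ishikawa cells and 712 CPM in untreated KLE cells, and in each panel the treated libraries of a line lie apart from its untreated ones.

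KLE cells with and without copper chloride were compared to ask the same question in the other line. The metallothionein MT1G had 2 counts in the untreated libraries and 898 in the treated ones, a ratio of 445 (95% counting interval 123 to 3680). Its fitted log2 fold change was 8.58 ± 0.29 SE, and 11.23 without KLE control 3. HSPA6 went from 2.17 ± 0.607 to 113 ± 15.3 CPM (mean ± SD, n = 3; log2 fold change 5.68 ± 0.21 SE) and HMOX1 from 3.29 ± 0.226 to 57.4 ± 5.38 CPM (mean ± SD, n = 3; 4.12 ± 0.10 SE). RRAD rose by 5.48 ± 0.25, ARC by 5.39 ± 0.17, and ANKRD1, a stress-responsive ankyrin repeat protein (ENSG00000148677, chromosome 10, 90912096 to 90921276), by 3.56 ± 0.11 on the log2 scale. IGFN1 rose by 3.48 ± 0.23 and the microtubule-associated MAP1A by 3.32 ± 0.10. FGF19, a secreted growth factor (ENSG00000162344, chromosome 11, 69698232 to 69704642), went from 64.1 ± 4.11 to 10.8 ± 0.521 CPM (mean ± SD, n = 3; log2 fold change −2.56 ± 0.07 SE). PPP1R1B, a phosphatase inhibitor, went from 215 ± 4.23 to 41.8 ± 6.45 CPM and MAP2K6, a kinase upstream of p38, from 32.6 ± 1.07 to 4.46 ± 0.297 CPM (mean ± SD, n = 3). NEURL1B and LRRC32 had log2 fold changes of −3.77 ± 0.18 and −3.05 ± 0.16, GPRIN3 of −3.02, the mucin MUC5B of −2.75 and SMR3B of −2.43. As the rule for naming them required, all 3 treated libraries lay beyond all 3 untreated ones, and their adjusted p ranged from 1.4e-30 for HMOX1 to 5.4e-06 for HSPA6 (edgeR quasi-likelihood test, Benjamini-Hochberg). Of 13031 genes tested, 3330 were higher and 3287 lower with copper, 6617 in all. The split was 2685 and 3943 with upper-quartile factors, 2859 and 3735 with library totals, and 2125 and 2682 with limma on log2(TPM + 1).

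In KLE cells 9 of 30 gene lists passed camera, and none kept its call with an estimated correlation, where 0 of 30 passed. Correlation alone does not account for these losses, since autophagy genes lost the call at an estimated correlation of −0.026, below the preset 0.01. All 31 members of the proteasome list rose (median log2 fold change 0.53; camera adjusted p = 1.7e-21, and 0.121 with an estimated correlation), and of the 41 genes of the KEGG set 37 rose and 2 fell (0.536 with an estimated correlation). PSMC4 went from 103 ± 4.36 to 175 ± 9.4 CPM and PSMD14 from 166 ± 3.88 to 264 ± 8.34 CPM (mean ± SD, n = 3). NRF2 targets rose in 26 cases and fell in 2 (median 0.76; adjusted p = 4.1e-17, and 0.0584 with an estimated correlation), among them OSGIN1 by 2.01, SRXN1 by 1.65 and GCLM by 1.49. The number that rose was 28 adjusted over the list alone. Heat shock genes rose in 23 cases and fell in 2, with 4 not called (median 0.40; adjusted p = 2.1e-11, and 0.121 with an estimated correlation), including HSPA1A by 2.80, HSPH1 by 1.42 and DNAJB1 by 1.19. Adjusted over the list alone, 23 rose and 3 fell. Autophagy genes rose in 18 cases and fell in 1 (median 0.26; adjusted p = 2.4e-05, and 0.0703 with an estimated correlation), with the cargo receptor SQSTM1 up by 1.29. Their number was 19 adjusted over the list alone. The hypoxia list had 12 genes that rose and 4 that fell (median 0.20; adjusted p = 0.0333, and 0.179 with an estimated correlation), with the vasodilator peptide gene ADM up by 0.76 and the glycolytic regulator PFKFB3 at −0.64. Without KLE CuCl2 2 its adjusted p was 0.0546. Of the G2 and M phase genes 27 fell, 3 rose and 3 were not called (median −0.34; adjusted p = 6.1e-11, and 0.0703 with an estimated correlation). The kinetochore gene CENPF went from 411 ± 30.4 to 185 ± 6.75 CPM and PTTG1 from 101 ± 9.42 to 49.6 ± 1.07 CPM (mean ± SD, n = 3), while HMMR rose by 0.40 and ANLN by 0.20. Estrogen-responsive genes fell in 9 cases and rose in 1, with 3 not called (median −0.69; adjusted p = 0.00252, and 0.179 with an estimated correlation), among them AGR2 at −1.41, PDZK1 at −1.30 and the chemokine CXCL12 at −1.27. The estrogen receptor ESR1 stood at 0.104 ± 0.0758 TPM in untreated and 0.246 ± 0.144 TPM in copper-treated KLE cells (mean ± SD, n = 3). Of the 13 protein-coding genes of the mitochondrial genome 8 fell, 0 rose and 5 were not called (median −0.38; adjusted p = 1.0e-06, and 0.524 with an estimated correlation). In this list 9 fell when adjusted over the list alone. MT-CO1, a cytochrome oxidase subunit, went from 17500 ± 1330 to 10000 ± 1050 CPM (mean ± SD, n = 3). MT-ND6 had a log2 fold change of −0.63 with an adjusted p of 0.0132 (edgeR, Benjamini-Hochberg), 0.0526 without KLE CuCl2 1 and 0.0509 without CuCl2 3.

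The copper-binding and copper-handling genes were read in KLE cells in the same way. All 4 tested metallothioneins of 12 rose (median log2 fold change 3.25; camera adjusted p = 4.2e-07, and 0.0703 with an estimated correlation), and the median is the same with MT1G at its lower bound. MT2A went from 712 ± 38.4 to 2970 ± 61.2 CPM, MT1X from 37.7 ± 5.61 to 367 ± 25.3 CPM and MT1F from 3.61 ± 0.143 to 33.4 ± 0.794 CPM (mean ± SD, n = 3). Of the 10 cuproptosis genes 4 rose, 1 fell and 5 were not called (median 0.13). MTF1 rose by 0.32 ± 0.06, DLD by 0.19 ± 0.04 and PDHB by 0.13 ± 0.05, and CDKN2A fell by 0.29 ± 0.05 (log2 ± SE). FDX1 had a log2 fold change of 0.16 ± 0.08, LIAS of 0.13 ± 0.09, LIPT1 of −0.13 ± 0.14, DLAT of 0.03 ± 0.04 and PDHA1 of −0.01 ± 0.04, with adjusted p between 0.0928 and 0.899 (edgeR, Benjamini-Hochberg). FDX1 had an adjusted p of 0.0438 without KLE CuCl2 1. In the copper transport list 6 genes rose, 7 fell and 8 were not called (median 0.01, mean −0.07; median −0.03 with upper-quartile factors and −0.02 with library totals). The copper-carrying ferroxidase CP went from 4.66 ± 0.387 to 1.03 ± 0.0575 CPM (mean ± SD, n = 3), and ATP7B, STEAP4 and STEAP3 fell, with values of −0.55 ± 0.09, −0.43 ± 0.11 and −0.25 ± 0.07. STEAP1 rose by 0.51 ± 0.12, COA6 by 0.39 ± 0.10, CUTC by 0.37 ± 0.10, SLC25A3 by 0.18 ± 0.03 and SOD1 by 0.15 ± 0.03, and SLC31A1 was at 0.00. The calls of ATP7A, ATOX1, PDHB, COX11 and SCO1 were marginal, with losses in several refits, among them DESeq2 and limma on log2(TPM + 1) with no filter. The copper exporter ATP7A (−0.25, adjusted p = 0.0237 by edgeR) had −0.24 and 0.132 with DESeq2. It was lost without KLE control 2 (−0.24, 0.0653), CuCl2 2 (−0.22, 0.0752) or CuCl2 3 (−0.23, 0.0638). The copper chaperone ATOX1 (0.18, adjusted p = 0.017) had 0.18 and 0.0853 with DESeq2 and 0.13 and 0.0725 with upper-quartile factors. It was lost without control 3 (0.14, 0.0983) or CuCl2 1 (0.13, 0.124). PDHB (adjusted p = 0.0202) had 0.14 and 0.075 with DESeq2 and 0.09 and 0.12 with upper-quartile factors. It was lost without control 2 (0.09, 0.174), control 3 (0.14, 0.052) or CuCl2 1 (0.12, 0.0686). COX11 (−0.17, adjusted p = 0.0323) had −0.17 and 0.108 with DESeq2. It was lost without controls 1 (−0.18, 0.0617), 2 (−0.14, 0.128) or 3 (−0.19, 0.0519) and CuCl2 2 (−0.15, 0.108) or 3 (−0.10, 0.226). SCO1 (−0.14, adjusted p = 0.0405) had −0.13 and 0.166 with DESeq2 and −0.14 and 0.058 with the replicate block. It was lost without controls 2 (−0.15, 0.0584) or 3 (−0.11, 0.153) and CuCl2 1 (−0.11, 0.156) or 3 (−0.13, 0.0883).

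**Figure D3:**
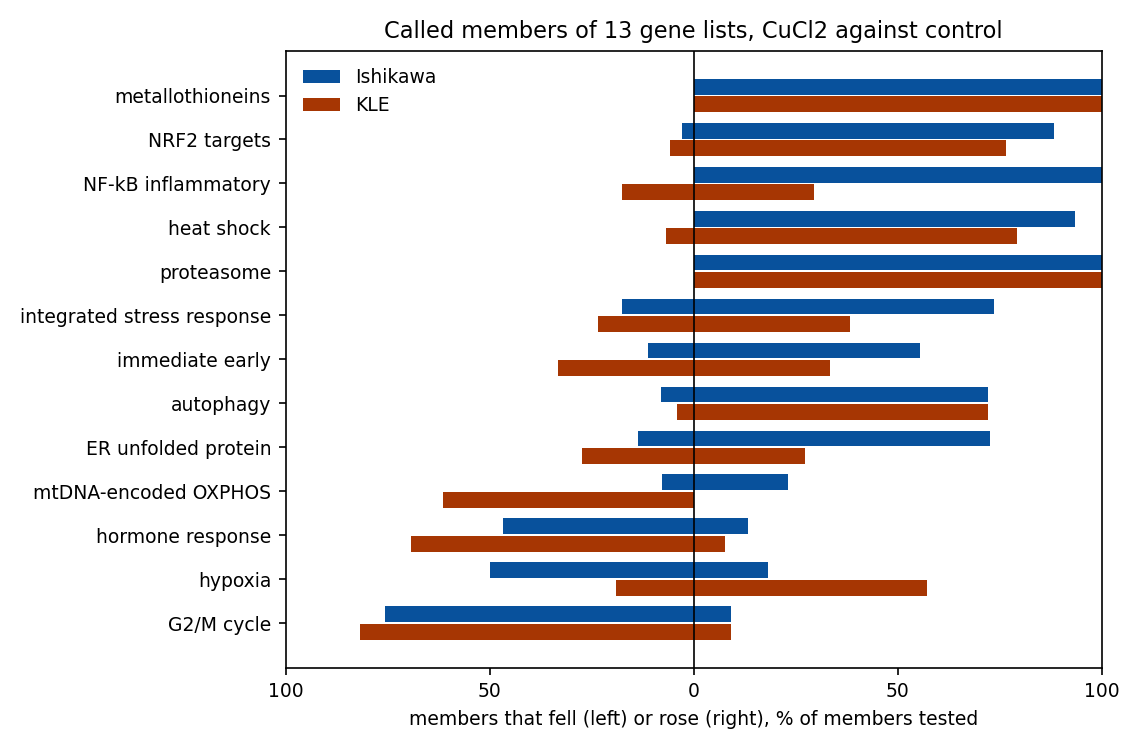
Share of tested members of 13 gene lists that rose (right) or fell (left) with copper at an adjusted p under 0.05, in percent, in Ishikawa (blue) and KLE cells (brown). All tested members of the proteasome and metallothionein lists rose in both lines, and most G2 and M phase genes fell in both.

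The responses of the lines were set side by side to ask how far they coincide. Of 12806 genes tested in both lines, 2425 were higher with copper in both, beside 1107 expected by chance (odds ratio 11.4), and 2470 were lower in both, beside 1163 expected (odds ratio 11.1). HSPA6, HMOX1, RRAD, ARC and MT2A were among the first, and NEURL1B, LRRC32, PTTG1, ATP7B and CDKN2A among the second. Of 5245 genes called in both lines 4895, or 93.3%, had the same direction and 350 the opposite one, among them STEAP1 and BNIP3. Log2 fold changes of the lines had a Pearson correlation of 0.72 and a Spearman correlation of 0.66 across genes, which are not independent replicates. The change was larger in Ishikawa cells for 83.9% of the genes called in the same direction, and the median KLE to Ishikawa ratio of log2 fold changes was 0.55. These values cover only genes called in both lines. Over all 12806 genes the median absolute log2 fold change was 0.41 in Ishikawa and 0.19 in KLE cells. The coefficient of variation among replicates was 6.4% in Ishikawa cells, 4% without Ishikawa control 2, and 3.6% in KLE cells.

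**Figure D4:**
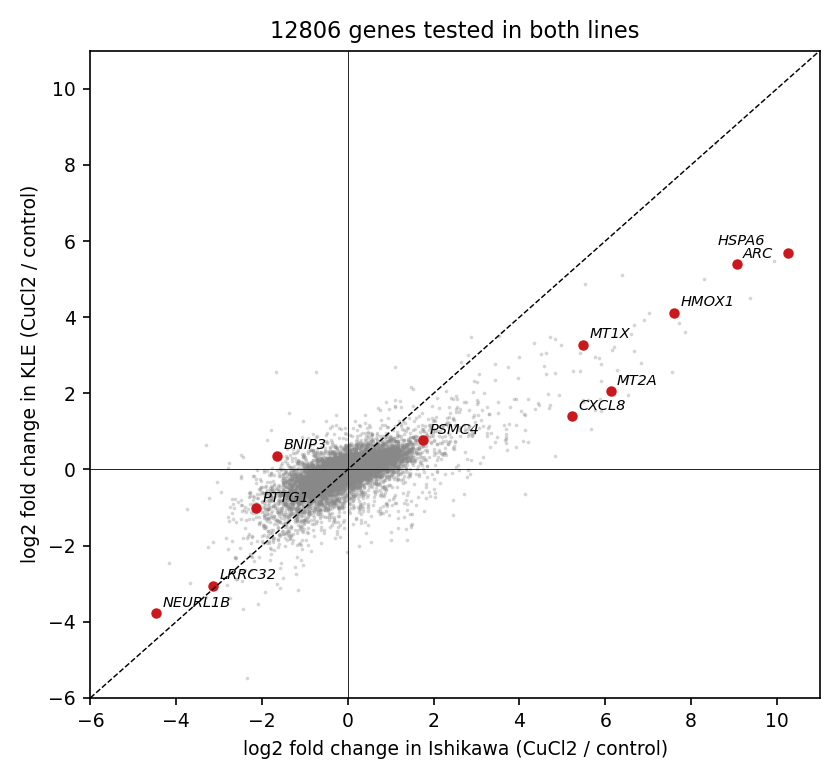
Log2 fold change with copper in Ishikawa (x axis) and KLE cells (y axis) for 12806 genes, 1 point per gene, with a dashed line of equality and 11 genes labelled. HSPA6 has values of 10.27 and 5.68.

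Several lists passed camera in neither line with TMM factors and no block. Counts in these lists depended on the scaling, and for some lists they are also given with upper-quartile factors and then with library totals. Zinc transporters rose in 8 cases and fell in 7 in Ishikawa cells (median 0.10, mean −0.04), and there rose in 5 and fell in 9, or rose in 4 and fell in 9, with those scalings (medians −0.01 and −0.05). They rose in 4 and fell in 6 in KLE cells, with the zinc exporter SLC30A1 up by 1.32 and 0.78. Lipoylation and TCA cycle genes rose in 11 and fell in 9 in Ishikawa cells (8 and 10, then 7 and 10) and rose in 8 and fell in 5 in KLE cells, with the isocitrate dehydrogenase IDH2 at −1.16 and −0.74. Iron-sulfur assembly genes rose in 7 and fell in 9 in Ishikawa cells and rose in 9 and fell in 2 in KLE cells (5 and 3, then 6 and 2). Targets of p53 rose in 9 and fell in 14 in Ishikawa cells (median −0.29), where CDKN1A rose by 0.63 and PHLDA3 fell by 1.21, and rose in 5 and fell in 10 in KLE cells. G1 and S phase genes rose in 13 and fell in 10 in Ishikawa cells (median 0.07, mean −0.02; 8 and 13 with a median of −0.04, then 7 and 13 with −0.08). In KLE cells they rose in 10 and fell in 9 (7 and 11, then 8 and 10). Cholesterol synthesis genes rose in 10 and fell in 8 in Ishikawa cells (7 and 13, then 6 and 13). In KLE cells they rose in 8 and fell in 5 (5 and 7, then 7 and 7). Iron and ferroptosis genes rose in 9 and fell in 6 in Ishikawa cells and rose in 7 and fell in 9 in KLE cells. Nuclear genes of oxidative phosphorylation rose in 18 and fell in 8 in Ishikawa cells, with 46 not called (5 and 18, then 3 and 23). In KLE cells they rose in 6 and fell in 7, with 59 not called (1 and 12, then 1 and 10). Apoptosis regulators rose in 9 and fell in 6 in Ishikawa cells (median −0.04, mean 0.28; 9 and 7, then 8 and 9), where PMAIP1 rose by 1.47, and rose in 7 and fell in 5 in KLE cells (median 0.04, mean −0.05; 5 and 5, then 6 and 5). Matrix and mesenchymal genes rose in 5 and fell in 8 in Ishikawa cells (median −0.17, mean 0.09), and rose in 5 and fell in 6 in KLE cells (median 0.01, mean −0.03). Epithelial genes rose in 4 and fell in 8 in Ishikawa cells (median −0.16, mean 0.18), and rose in 7 and fell in 4 in KLE cells. Ribosomal protein genes rose in 24 and fell in 7 of 76 in Ishikawa cells (7 and 17, then 5 and 23). Their camera adjusted p there was 0.136, and 0.869 with an estimated correlation, but 0.0464 with the replicate number as a block and 0.0154 without CuCl2 2. They rose in 12 and fell in 20 in KLE cells (6 and 29, then 7 and 27). Replication-dependent histone genes rose in 7 and fell in 0 of 12 in Ishikawa cells (median 0.91). Their camera adjusted p was 0.0671, and 0.261 with an estimated correlation, but 0.024 with upper-quartile factors and 0.0158 with library totals. In KLE cells none of 12 was called. Of the fibroblast markers 0 of 9 were called in Ishikawa cells and 1 fell in KLE cells, where the list had an adjusted p of 0.0297 without KLE control 1. On all libraries its camera adjusted p was 0.386, and 0.909 with an estimated correlation. Stromal transcripts, possibly foreign to the cells, summed to 25.7, 61.9 and 64.1 CPM in KLE controls 1, 2 and 3. In KLE CuCl2 1, 2 and 3 they summed to 36.6, 37 and 17.4 CPM. Of the endothelial markers 1 rose in Ishikawa cells and 2 fell in KLE cells, and of the leukocyte markers 2 rose in Ishikawa cells and 1 rose in KLE cells, where the list was too short to test. Adjusted over the list alone, the counts that differed were 10 p53 targets that rose, 16 nuclear oxidative phosphorylation genes that rose and 6 that fell, and 20 ribosomal protein genes that rose and 5 that fell in Ishikawa cells, and in KLE cells 9 integrated stress response genes, 10 G1 and S phase genes, 5 nuclear oxidative phosphorylation genes, 7 matrix and mesenchymal genes and 0 fibroblast markers that fell, and 14 integrated stress response genes and 1 nuclear oxidative phosphorylation gene that rose. In KLE cells the median and mean of zinc transporters were 0.01 and −0.01 and those of lipoylation and TCA cycle genes 0.04 and −0.01, and the unfolded protein response list had a median of 0.01 and a test direction downward. With upper-quartile factors the KLE medians of these lists were −0.04, −0.01 and −0.03, that of matrix and mesenchymal genes was −0.03 and that of apoptosis regulators −0.01. Lists called in a single line had other values in the other. In Ishikawa cells hypoxia genes rose in 4 and fell in 11 (median −0.22; adjusted p = 0.13), estrogen-responsive genes rose in 2 and fell in 7, and mitochondrially encoded genes rose in 3 and fell in 1 (2 and 1 with upper-quartile factors, 2 and 4 with library totals). In KLE cells integrated stress response genes rose in 13 and fell in 8, unfolded protein response genes rose in 6 and fell in 6 (3 and 7 with upper-quartile factors), NF-kB and inflammatory genes rose in 5 and fell in 3 (median −0.07, mean 0.04), and immediate-early genes rose in 6 and fell in 6.

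The difference between the copper responses was tested directly, as the KLE log2 fold change minus the Ishikawa one, to ask which genes responded differently in the lines. The carboxypeptidase gene CPM (ENSG00000135678, chromosome 12, 68842197 to 68971570) went from 21.9 ± 1.05 to 3.03 ± 0.276 CPM in Ishikawa cells and from 7.69 ± 1.09 to 7.94 ± 0.56 CPM in KLE cells (mean ± SD, n = 3; difference 2.90 ± 0.18 SE). BNIP3, a mitophagy receptor (ENSG00000176171, chromosome 10, 131966455 to 131982013), went from 48 ± 1.29 to 14.9 ± 0.543 CPM in Ishikawa cells and from 35.5 ± 1.21 to 45.5 ± 4.28 CPM in KLE cells (mean ± SD, n = 3; difference 2.05 ± 0.10 SE). The difference was 2.77 ± 0.18 for SLC1A1, 2.14 ± 0.29 for the receptor kinase KIT, 1.97 ± 0.17 for AFAP1L1 and 1.96 ± 0.27 for SRPX. Clusterin, the extracellular chaperone encoded by CLU (ENSG00000120885, chromosome 8, 27596917 to 27615031), went from 2.77 ± 0.946 to 136 ± 7.87 CPM in Ishikawa cells and from 6.51 ± 0.891 to 19.2 ± 0.716 CPM in KLE cells (mean ± SD, n = 3; difference −4.15 ± 0.21 SE). The difference was −4.92 ± 0.31 for CRYAB, −4.53 ± 0.73 for HSPA6, −4.53 ± 0.66 for the growth factor IGF2, −4.38 ± 0.83 for RRAD and −4.80 ± 1.16 for USP17L2. MT2A, at 712 CPM in untreated KLE cells, had a difference of −4.02 ± 0.19 and HMOX1 of −3.43 ± 0.21. Adjusted p for these genes ranged from 7.8e-13 for BNIP3 to 0.00178 for USP17L2 (edgeR quasi-likelihood test, Benjamini-Hochberg). Of 13663 genes 3358 had a positive and 2848 a negative difference, 6206 in all. The split was 2942 and 3196 with RLE factors, 2540 and 2948 with DESeq2, 2935 and 3069 without a count filter, and 4151 and 2349 with library totals. Without Ishikawa control 2 the difference was −4.29 for CRYAB, −3.75 for HSPA6, −3.82 for IGF2 and −3.58 for RRAD, and without Ishikawa control 3 it was −5.31 for HSPA6, −5.12 for IGF2 and −5.65 for RRAD. It was −3.94 for IGF2 without KLE control 3, and −3.61 for USP17L2 without KLE control 2, with an adjusted p of 0.167.

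Among the lists 14 of 31 passed camera for the difference between responses, and 8 of them kept the call with an estimated correlation, or 7 with the group columns in another order. The KLE response was below the Ishikawa one for 24 of 30 heat shock genes (median difference −0.89; adjusted p = 5.7e-17, and 0.0356 with an estimated correlation) and for 25 of 31 members of the proteasome list (median −0.48; adjusted p = 1.4e-13, and 0.0352 with an estimated correlation). For the 41 genes of the KEGG proteasome set the adjusted p was 0.233 with an estimated correlation, with 30 below and 1 above. It was also lower for 16 of 18 NF-kB and inflammatory genes (median −1.34; adjusted p = 3.8e-08, and 0.0375 with an estimated correlation), including CXCL8 with a difference of −3.77 and CCL20 with −3.79. NRF2 targets had 19 negative and 2 positive differences (median −0.49; adjusted p = 5.3e-07, and 0.0352 with an estimated correlation), autophagy genes 12 and 2 (median −0.16; 0.00593, and 0.0434; 7 and 5 with library totals) and unfolded protein response genes 13 and 2 (median −0.25; 1.3e-04, and 0.0352). The KLE value was above the Ishikawa one for 22 of 33 G2 and M phase genes, with 1 below (median 0.33; adjusted p = 4.1e-07, and with an estimated correlation 0.0483, or 0.0526 and not called with the group columns in another order), and for 14 hypoxia genes, with 1 below (median 0.28; adjusted p = 8.6e-05, and 0.0352 with an estimated correlation). The cuproptosis list had 1 positive difference (CDKN2A, 0.37) and 2 negative ones (DLD, −0.60, and MTF1, −0.69) and did not pass (adjusted p = 0.646), with 3 positive and 2 negative ones under library totals. Calls lost with an estimated correlation were those of integrated stress response genes, with 21 negative and 5 positive differences (median −0.52; adjusted p = 0.266 with an estimated correlation), immediate-early genes with 12 and 2 (median −0.78; 0.134), mitochondrially encoded genes with 6 and 0 (median −0.50; 0.409), metallothioneins with 3 and 0 (median −2.55; 0.0757) and iron and ferroptosis genes with 10 and 3 (median −0.19; 0.0826; 8 and 4 with library totals). Replication-dependent histone genes had 5 negative differences and 9 genes not called (median −1.34; adjusted p = 0.0331, and 0.409 with an estimated correlation). Their adjusted p was 0.0555 with RLE factors, 0.0841 without Ishikawa control 2, 0.175, 0.093 and 0.0741 without Ishikawa CuCl2 1, 2 and 3, 0.105 without KLE control 1 and 0.0568 without KLE CuCl2 3. Ribosomal protein genes passed with an adjusted p of 0.00115 without Ishikawa CuCl2 2, 0.0461 without KLE control 1 and 0.0217 without KLE CuCl2 3, and fibroblast markers with 0.0487 without Ishikawa control 3. On all libraries the camera adjusted p of these lists was 0.176 and 0.12, and 0.819 and 0.708 with an estimated correlation. Adjusted over the list alone, 27 heat shock, 17 NF-kB and inflammatory, 22 integrated stress response and 11 iron and ferroptosis genes had a negative difference.

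Untreated KLE and Ishikawa cells were compared to ask how the lines differed before copper, as KLE minus Ishikawa. NT5E, the ectoenzyme CD73 (ENSG00000135318, chromosome 6, 85449584 to 85495791), stood at 2.18 ± 0.62 CPM in Ishikawa and 180 ± 3.14 CPM in KLE cells, and PLAT, the tissue plasminogen activator (ENSG00000104368, chromosome 8, 42175233 to 42207724), at 0.681 ± 0.0763 and 66.4 ± 1.9 CPM (mean ± SD, n = 3). LHX1, a LIM homeobox factor, was higher in KLE cells by 7.96 ± 0.20, FAM83A by 6.61 ± 0.20 and ELFN2 by 6.44 ± 0.18 (log2 ± SE). CALCRL, a receptor for adrenomedullin and calcitonin gene-related peptide (ENSG00000064989, chromosome 2, 187343129 to 187448460), stood at 90.5 ± 5.32 CPM in Ishikawa and 5.07 ± 0.673 CPM in KLE cells (mean ± SD, n = 3). The log2 difference was −7.16 ± 0.34 for the synaptic protein LRRTM4, −4.07 ± 0.16 for chromogranin A (CHGA) and −3.75 ± 0.22 for NEXMIF. Adjusted p for these genes ranged from 1.6e-25 for NT5E to 8.6e-13 for NEXMIF (edgeR quasi-likelihood test, Benjamini-Hochberg). Of 13663 genes 3343 were higher and 3495 lower in KLE cells, 6838 in all. Group means of log2 CPM had a Pearson correlation of 0.958 across genes between the untreated lines, of 0.939 between untreated and treated Ishikawa cells and of 0.98 between untreated and treated KLE cells. By more than 2-fold 1512 genes, or 11.1%, differed between the untreated lines, beside 2338, or 17.1%, between untreated and treated Ishikawa cells and 884, or 6.5%, between untreated and treated KLE cells.

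In the untreated lines 9 of 31 lists passed camera, and 0 did so with an estimated correlation. NF-kB and inflammatory genes were higher in KLE cells in 14 cases and lower in 0 (median 1.13; adjusted p = 2.7e-06, and 0.264 with an estimated correlation), with the cytokines IL1B higher by 5.65 and LIF by 3.59. Proteasome subunits were higher in 26 and lower in 0 cases (median 0.21; adjusted p = 2.7e-06, and 0.264 with an estimated correlation). Metallothioneins were higher in 3 of 4 cases (median 2.71; adjusted p = 0.00584, and 0.264 with an estimated correlation). Epithelial genes were higher in 10 cases and lower in 1 (median 0.43; adjusted p = 0.00194, and 0.264 with an estimated correlation), among them the keratin KRT19 by 1.03. Integrated stress response genes were higher in 19 and lower in 6 (median 0.23; adjusted p = 0.00194, and 0.499 with an estimated correlation), immediate-early genes in 12 and 2 (median 0.75; 0.00584, and 0.499) and heat shock genes in 14 and 4 (median 0.21; 0.0201, and 0.499). Ribosomal protein genes were lower in 24 cases and higher in 2 of 76 (median −0.08; adjusted p = 0.0362, and 0.558 with an estimated correlation), with RPL13A at −0.41 and RPS21 at 0.52. Their adjusted p was 0.0815 without Ishikawa control 1, 0.111 without Ishikawa control 3 and 0.109 without KLE control 3. Unfolded protein response genes were higher in 10 and lower in 2 cases (median 0.05; adjusted p = 0.282 with an estimated correlation). The adjusted p of this list was 0.04999, and without any 1 library other than Ishikawa control 2 or KLE control 2 it lay between 0.0582 and 0.116. On all libraries it was 0.0503 with the replicate block, 0.0539 with RLE factors, 0.0571 with upper-quartile factors and 0.0796 with library totals. Replication-dependent histone genes passed with an adjusted p of 0.0292 without KLE control 2, 0.0438 without KLE control 3 and 0.0422 with library totals. Lipoylation and TCA cycle genes passed with 0.044 with library totals, and mitochondrially encoded genes with 0.0403 without Ishikawa control 2. On all libraries with an estimated correlation the camera adjusted p was 0.499 for the histone, 0.282 for the lipoylation and 0.9 for the mitochondrially encoded genes. Adjusted over the list alone, 15 NF-kB and inflammatory genes were higher, and 23 ribosomal protein genes were lower and 1 higher.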

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

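Tests chosen only after the result was seen are those of the metallothionein level, of a trace of RNA from 1 mixed tissue, of KLE CuCl2 3 against the other libraries, of fibroblasts growing in the cultures and of a separate handling of Ishikawa control 2; the others were chosen before.

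The copper responses differed between KLE and Ishikawa cells for 6206 genes by the test of the difference itself (edgeR). Of 100 drawn splits of the libraries 5 gave at least as many genes, the real one included, and the highest other gave 7171. The count of 5 does not exclude chance. The 4 others are among the 19 splits that leave the treatment labels of 1 line whole and so carry that line's own response, a structure of the samples. The 80 splits that mix treated and untreated libraries in both lines gave at most 0 genes. Such mixing puts the copper response into the spread within groups, so neither kind of split decides about chance.

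Each value below is a KLE minus Ishikawa log2 response that differed by that test. Chaperone and stress genes had −4.53 (HSPA6), −3.97 (HSPA1A), −4.92 (CRYAB), −4.15 (CLU), −3.43 (HMOX1), −1.65 (AKR1B10), −2.58 (ATF3), −1.79 (SESN2), −3.77 (CXCL8) and −3.79 (CCL20). Proteasome genes had −0.93 (PSMC4), −1.08 (PSMD12) and −0.64 (PSMD14), and mitotic genes 1.36 (KIF20A), 1.18 (PTTG1) and 0.53 (CENPF). Metal-binding and copper-handling genes had −4.02 (MT2A), −2.95 (MT1F), −2.15 (MT1X), −0.69 (MTF1), −0.23 (SLC31A1), −0.16 (SLC25A3), −0.23 (SOD1), −0.48 (COX19), 0.30 (COX11), 0.22 (SCO1), 1.41 (SCO2), 1.41 (STEAP1), 1.21 (STEAP2), 0.88 (STEAP3), 0.47 (CUTC) and −2.09 (CP). Of the cuproptosis genes, DLD had −0.60 and CDKN2A 0.37. Other genes that rose in a line had −4.38 (RRAD), −4.80 (USP17L2, −3.61 and not called without KLE control 2), −3.62 (ARC), −2.98 (ANKRD1), −0.96 (MAP1A) and −4.53 (IGF2). Genes that fell in a line had 0.76 (NEURL1B), 1.76 (SEMA3D), 1.30 (TTYH2), 2.77 (SLC1A1), 2.90 (CPM), 1.58 (TNFRSF19), −1.30 (GPRIN3), −1.50 (MUC5B), −1.28 (FGF19), −1.63 (SMR3B), −0.48 (PPP1R1B), −0.47 (MT-CO1), 2.14 (KIT), 2.05 (BNIP3) and 1.96 (SRPX), and AFAP1L1 had 1.97.

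Lists whose responses differed at the preset correlation of camera and with an estimated one had median differences of −0.89 (heat shock), −0.48 (proteasome), −1.34 (NF-kB and inflammation), 0.33 (G2 and M phase, not called with the group columns in another order, adjusted p = 0.0526), −0.49 (NRF2 targets), 0.28 (hypoxia), −0.25 (unfolded protein response) and −0.16 (autophagy). Lists that differed at the preset correlation alone had −0.52 (integrated stress response, adjusted p = 0.266 with an estimated correlation), −0.78 (immediate-early, 0.134), −0.50 (mitochondrially encoded, 0.409), −2.55 (metallothioneins, 0.0757), −0.19 (iron and ferroptosis, 0.0826) and −1.34 (replication-dependent histones, 0.409).

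More genes were called in Ishikawa than in KLE cells, 9228 against 6617, and changes were larger. Library depth is argued against by counts thinned to the smallest total, 14050275, where the ratio of calls was still 1.39, and Ishikawa control 2 by the ratio of 1.42 without it. In each line 10 splits of the 6 libraries are too few for a share under 0.05: the real split alone (1 of 10) gave 9228 and 6617 genes, and the highest other gave 0 in each line. A higher level of metallothioneins in untreated KLE cells, MT2A at 712 against 12.5 CPM, is a candidate explanation for the median KLE to Ishikawa ratio of log2 fold changes of 0.55, but with 1 line of each level it cannot be told apart from any other difference between the lines. A difference in sensitivity between the lines stays open as untested.

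Transcripts of untreated Ishikawa and KLE cells had a correlation of 0.958 across genes. It was 0.939 between untreated and treated Ishikawa cells and 0.98 between untreated and treated KLE cells. Between the untreated lines 6838 genes differed (1 of 10 splits, the real one, with the highest other at 0, too few splits for a share under 0.05). No other line was measured, so these values do not show whether the lines are more alike than others. PAX8 stood at 438 TPM in both, CDH1 at 206 and 196, EPCAM at 841 and 1040, and VIM at 6 and 11.3. ESR1 (0.124 and 0.104 TPM) and PGR (0.144 and 0.0793 TPM) were low in both. That both cultures hold 1 cell line could not be told apart from their holding related lines. Log2 differences ran together along chromosomes 1.92 times as much as shuffled genes, short of the bound of more than 2 set beforehand. The copper responses gave 1.40 and 1.37. The SD of medians over runs of 50 neighbouring genes was 0.106, above the highest of 1000 shuffles (0.063). The copper responses passed their shuffles too (0.147 against 0.119 in Ishikawa cells, 0.064 against 0.054 in KLE cells). The lowest medians, −0.39 and −0.37, were of adjoining runs on chromosome 12. The highest, 0.39 and 0.48, were of adjoining runs on chromosome 20. The source of these shifts was not tested. KLE cells in the Ishikawa cultures are argued against, since the 5th lowest of the abundant KLE genes was at 1.92% of its KLE level in Ishikawa cells. Ishikawa cells in the KLE cultures may contribute a small share at most. The corresponding value was 18.2%, but likeness of the lines gives the same value. A share cannot exceed the lowest level found, and LRRTM4 stood at 0.659% and CALCRL at 5.62% of their Ishikawa levels. For LRRTM4 this rests on few counts, 0.108 CPM in KLE cells. Line identity was not tested by genotype here, and per the labels both lines had been authenticated.

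Transcripts of connective tissue stood in 11 of the 12 libraries, with stromal counts of 257 to 1008 (DCN 67 to 364) and plasma-cell counts of 21 to 715 (IGKC 12 to 208), whereas Ishikawa control 2 had 18 stromal counts, from COL1A2, COL3A1 and MGP of the 6 genes, and 0 plasma-cell counts, and glandular secretory transcripts had 13 to 303 counts beside 4. Fibroblasts growing in the cultures as the only source are argued against by the plasma-cell transcripts, whose lowest count in the 11 libraries was 21. Fibroblasts beside another source are not excluded, since both could be present. A trace of RNA from a mixed tissue is a candidate explanation: stromal and plasma-cell CPM had a Pearson correlation of 0.93 across the 11 libraries (permutation p = 3.0e-05, Spearman 0.86 with permutation p = 0.00123, 1 relation computed; 0.86 without the 2 farthest libraries and 0.97 in the 6 KLE libraries). The same mixture in KLE CuCl2 3, the library whose low plasma-cell count prompted the test, is argued against by its plasma-cell to stromal ratio of 0.0817 (95% interval 0.0497 to 0.128, for counting error only), beside 0.443 to 1.03 in the other 10. Ishikawa control 2, with a DCN count of 0 in the deepest library, stands apart by more than counting chance. Chi-square per degree of freedom was 8.45 and 12.85 for its pairs with controls 1 and 3, and 2.73 between those. On the third principal component (5.1% of variance) it lies at 27.8, beside 2 and −2.8 for the other untreated Ishikawa libraries. That component also parts treated (15.1, 9.9 and 20.2) from untreated KLE libraries (−17.1, −16.7 and −20.9). Whether Ishikawa control 2 was handled or sequenced apart stays open, since the labels give no batch. No biological explanation was tested.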

How the results depend on the processing

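Refits chosen after seeing the data were those of the gene lists under other scalings, other column orders and left-out libraries, and with the replicate block for the untreated lines, and the counts of targeted genes. In no refit did the direction of a named gene reverse where the main fit or the refit called it. Changes of sign in genes called by neither fit were not counted. The side of the threshold was kept in 897 of 918 refits of 51 genes in Ishikawa cells. In KLE cells it was kept in 848 of 900 refits of 50 genes, for the response difference in 251 of 252 and for the untreated lines in 200 of 200. Requiring an absolute log2 fold change of at least 1 left 2224 genes in Ishikawa cells, 710 in KLE cells, 941 for the response difference, 1458 for the untreated lines and 495 called in the same direction in both lines, because fewer genes pass 2 criteria. With an estimated correlation 1 list passed in Ishikawa cells, 0 in KLE cells, 8 for the response difference and 0 for the untreated lines, and with the group columns in another order 7 and 0 in the last 2, where the G2 and M phase list had an adjusted p of 0.0526. Lists with an estimated correlation under the preset 0.01 lost calls too, such as NF-kB and inflammatory (−0.038) and autophagy genes (−0.02) in Ishikawa cells. A lost call is therefore not a measure of correlation within a list. The counts come from fits of 6 libraries in each line and of 12 otherwise, so they do not rank the comparisons. With fry 20, 15, 20 and 21 lists passed, and 19 and 20 in the last 2 comparisons with the other order. This test compares no list with other genes. The p53 targets of Ishikawa cells passed fry upward (adjusted p = 0.031) with a median of −0.29; the cause was not tested. Of the targeted copper and metallothionein genes 22 were called in KLE cells, and 14 with limma on log2(TPM + 1) and no filter; the cause was not tested. Without 1 library the counts ranged from 8546 to 9408 in Ishikawa cells, 5844 to 6238 in KLE cells, 5598 to 6530 for the response difference, 6035 to 6842 for the untreated lines and 4453 to 5015 shared. Called lists then ranged from 9 to 11, 8 to 10, 13 to 15 and 7 to 10, and targeted genes from 21 to 22, 19 to 21, 15 to 18 and 16 to 19 in the same order. Treating the replicate number as a block gave 9355, 6193, 6132 and 6775 genes. Deviations from the group mean had correlations of 0.082, 0.201 and 0.081 between copper and untreated Ishikawa libraries of 1 number. Unlike numbers gave −0.167 to 0.09 there. In KLE cells libraries of 1 number gave −0.127, −0.053 and −0.105, beside −0.007 to 0.109 for unlike ones. Since libraries of 1 number tended to go together in Ishikawa cells alone, the numbers were not read as pairs. Depth limits genes with few counts in untreated cells, such as MT1G, USP17L2 and NEFM.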

Other observations

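The terms below come from the pathway and process columns of the deposited table and were tested with camera only after the data had been seen, as terms of 10 to 300 genes. Genes of homophilic cell adhesion, mostly cadherins and protocadherins, fell in 54 and rose in 9 of 94 cases in Ishikawa cells (median log2 fold change −0.63; camera adjusted p = 0.00639, and 0.904 with an estimated correlation) and fell in 52 and rose in 13 of 91 cases in KLE cells (median −0.45; 0.00213, and 0.795). CDH6 had values of −1.61 ± 0.12 and −1.72 ± 0.15 and PCDHB11 of −1.63 ± 0.12 and −1.52 ± 0.15 in Ishikawa and KLE cells (log2 ± SE), whereas the adhesion molecule L1CAM rose by 2.79 ± 0.13 and 0.87 ± 0.09. Genes of anterior and posterior pattern specification fell in 39 and rose in 6 of 66 cases in Ishikawa cells (median −0.47; adjusted p = 0.00826, and 0.904 with an estimated correlation) and fell in 34 and rose in 2 of 68 in KLE cells (median −0.31; 0.00213, and 0.795). Among them the homeobox factor EMX2 had values of −1.18 ± 0.09 and −1.35 ± 0.17. Heparan sulfate synthesis genes fell in 15 and rose in 2 of 17 cases in Ishikawa cells (median −0.65; adjusted p = 0.00815, and 0.528 with an estimated correlation), with the sulfotransferase HS6ST1 at −1.26 ± 0.07.

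Subunits of the vacuolar proton pump, grouped as synaptic vesicle lumen acidification, rose in 11 of 15 cases in Ishikawa cells (median 0.78; adjusted p = 0.00669, and 0.904 with an estimated correlation) and in 12 of 14 in KLE cells, where 1 fell (median 0.29; 0.0115, and 0.795). ATP6V0A1 rose by 1.32 ± 0.06 and 0.50 ± 0.05 and ATP6V1A by 1.03 ± 0.05 and 0.32 ± 0.04. Ribosome biogenesis genes rose in 39 and fell in 1 of 71 cases in KLE cells (median 0.16; adjusted p = 1.0e-04, and 0.554 with an estimated correlation) and rose in 38 and fell in 12 of 72 in Ishikawa cells (median 0.20; 0.0401, and 0.528), among them the ribosome maturation factor SBDS by 0.56 ± 0.04 in KLE and 1.36 ± 0.05 in Ishikawa cells. Spliceosome genes rose in 79 and fell in 15 of 130 cases in Ishikawa cells (median 0.24; adjusted p = 3.4e-04, and 0.429 with an estimated correlation), with SLU7 up by 1.39 ± 0.06, and their responses were lower in KLE cells in 59 cases and higher in 17 (median difference −0.17; 4.2e-04, and 0.233). Genes of canonical glycolysis rose in 8 and fell in 0 of 11 cases in KLE cells (median 0.30; adjusted p = 0.0213, and 0.795 with an estimated correlation), with PKM up by 0.48 ± 0.03, and their response exceeded the Ishikawa one in 9 cases (median difference 0.34; 0.00401, and 0.799).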
